A study of Mus musculus with 2 samples.

How the data were processed

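The series comprised 2 libraries from CGR8 mouse embryonic stem cells cultured with 15% serum replacement on 0.1% gelatin, 1 from an anti-Bcl3 immunoprecipitation of enzyme-digested nuclei and 1 from input, per the labels' protocols. With 1 library per group there were no replicates, so no test compares samples. Every test below compares peaks or genes within 1 list, and peaks and genes are not replicates of the experiment. The input library was not analysed here on its own. Read counts were not used here, so the depth is unknown, and the intervals given cover counting error over peaks or genes only.

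The authors' peak workbook was used, with positions in mm9 per the submitters' processing notes. The aligner, the peak caller, its thresholds and the way the input entered the call are not given in the sources used here. Per the file headers, each peak carries a false discovery rate, treated as a q-value. The deposited log2 fold change is the greatest within the peak, and the header names no denominator. The deposited maxT score is the greatest value of a T statistic in the peak, and it stayed between 1.21 and 1.22 times the log2 fold change in all peaks, so it was not ranked separately. The deposited −log10 value is that of the smallest Poisson p-value in the peak, and it reached a ceiling of 100 in 1 peak. Peaks were deposited on a grid of 25 bp. In 117 peaks the deposited left boundary lay to the right of the right boundary, so start, end and summit positions were used and those boundaries were not.

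A deposited wider annotation gives up to 21 RefSeq genes per peak with signed distances, and a deposited closest-transcript sheet gives exons for 623 peaks and none for 507. Those 623 peaks had their midpoint inside the listed transcript (443) or at most 7954 bp from it. A gene farther away than that was therefore never a closest gene. Distances to the closest transcription start site (TSS) were taken from the wider annotation, measured from the peak midpoint, and the place of a summit in an exon or intron from the exons of the closest transcript. Both sheets sometimes give different transcripts of a gene, so distances can differ between them. A spreadsheet program had turned 2 gene symbols into dates, and these were recovered through their RefSeq identifiers. The class counts of the authors' deposited table were recounted from its entries per peak and were equal. Gene names were matched to a RefSeq gene table of GRCm38.p6, used for names, gene class, gene counts per chromosome and gene neighbours only, never for coordinates. All 623 closest-transcript entries matched, to 592 genes, of which 552 were protein coding. In the wider annotation 14536 of 14602 entries matched.

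The share of peaks within 5 kb of a TSS was given with exact Clopper-Pearson 95% intervals. Upstream and downstream counts were compared by a two-sided exact binomial test. Median log2 fold enrichment near and far from a TSS was compared by a two-sided permutation test with 100000 resamples. For 21 gene lists of 579 entries (547 distinct genes), all matched, two-sided Fisher's exact tests compared list members with the other protein-coding genes of 21900, with Benjamini-Hochberg adjustment over the lists. The lists covered core, naive and primed pluripotency, LIF and STAT3 signalling, NF-κB pathway and targets, WNT, FGF and MAPK, TGF-β and BMP, neural, mesoderm, endoderm, trophectoderm, germ cell, Hox, Polycomb and chromatin, cell cycle, apoptosis, ribosomal protein, fibroblast, and liver and muscle genes. This was done for the closest gene and for genes with a peak within 5 kb of the TSS. Peaks per chromosome were compared with protein-coding genes per chromosome by a Monte Carlo multinomial test. The list test was checked on simulated data with 200 runs per setting and passed a list without enrichment in 0.0% (naive pluripotency) and 0.5% (ribosomal proteins) of runs. The simulation gave all genes outside the raised list an equal chance. In the wider annotation, 16.7% of the longest 885 genes were the closest gene of a peak, against 3.7% of the shortest 885. The check therefore does not cover a bias by gene length.

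Lists, loci, tests and the 5 kb window were chosen before the data were examined. The planned random placement of peaks and the planned search for the κB motif need an mm9 genome, which was not used here, and neither was run. As a substitute, chosen after the data were seen, peaks were shifted by 20, 50 and 100 kb to either side and the distances recomputed from the gene starts listed in the wider annotation, with exact McNemar tests. Positions that left the annotated region were dropped, leaving 1005 to 1027 peaks.

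Peaks were named by a rule fixed in advance. It took the 10 with the greatest fold enrichment, the 10 with the greatest Poisson score, the 18 fixed loci, up to 4 genes per list with a peak within 5 kb of the TSS or otherwise up to 2 at any distance, and the 5 genes with the most peaks. Alternatives were the 565 peaks with the greater score or fold enrichment, leaving out the top 1% of peaks, windows of 1 and 10 kb, another gene background, every gene of the wider annotation, merging of peaks within 1000 bp, and a false discovery rate of at most 5%. The 238 peaks of the lowest false discovery rate, distances from the closest-transcript sheet, closest genes restricted to those also in the wider annotation, and chromosome length were added after the data were seen. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.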

Results

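Chromatin recovered with an anti-Bcl3 antibody was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in CGR8 cells, a mouse embryonic stem cell line. Bcl3 is an atypical member of the IκB family, which acts in the nucleus through the NF-κB subunits p50 and p52. The cells were kept undifferentiated on gelatin with leukemia inhibitory factor (LIF) at 1000 U/ml. The series held 1 Bcl3 ChIP library and 1 input library, so there were no replicates and no spread between libraries could be measured. The authors' list of 1130 peaks from the ChIP library was used, with positions in mouse build mm9. The input library was not analysed here on its own, and the read depth of both libraries is unknown. Fold enrichment, score and false discovery rate of each peak are the authors' values. The header names no denominator for the fold enrichment.

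The strongest peak lay in intron 7 of Myst2 (Kat7), on chromosome 11 at 95146050 to 95146424, with a log2 fold enrichment of 4.02. Over the 1130 peaks the log2 fold enrichment ran from 2.48 to 4.02, with a median of 2.93, which is 7.62-fold. Peaks were short, with a median length of 200 bp and a range of 100 to 875 bp. The −log10 Poisson p had a median of 5.80, and 29 peaks exceeded 10. Fold enrichment and Poisson score ranked the peaks differently across peaks (Spearman's rho −0.012, permutation p = 0.694), whereas fold enrichment rose with peak length (rho 0.75). Peaks within 1 library are not independent replicates. The false discovery rate was 0.179 for the 238 top-ranked peaks, never fell with rank, and reached 0.619 at the last peak, and 0 peaks had a rate of at most 5%. Read as a cumulative share, these rates correspond to 42.5 false peaks among the top 238 and 699.8 among all 1130.

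Several of the 10 peaks with the greatest fold enrichment lay at gene starts, whereas 24.8% of the 113 highest-ranked peaks lay within 1 kb of a start. After Myst2, the peak of Nme1 had a log2 fold enrichment of 3.95 and lay in intron 1, 147 bp downstream of the transcription start site (TSS). The peak of Dcp1a (3.89) lay in coding exon 1, 99 bp downstream of the TSS. Trim52 (3.83) had its peak in the 5' UTR 160 bp from the TSS, and Pqlc1 (Slc66a2, 3.78) in intron 1 at 143 bp. D230025D16Rik (3.77) had a 5' UTR peak 150 bp from the listed TSS. The peaks of Gtf3c6 (3.76) and C330046G13Rik (Platr7, 3.74) lay 1004 and 530 bp upstream. Esrrb, an orphan nuclear receptor gene of the pluripotency network, ranked 8 with a log2 fold enrichment of 3.77, on chromosome 12 at 87839550 to 87839899. That peak lay in intron 3, 77.1 kb from the start of the listed transcript. The peak at rank 4 (3.87), on chromosome 7 at 146549800 to 146550449, had no closest transcript, and the nearest start, of Inpp5a, was 24.9 kb away. All 10 had a false discovery rate of 0.179.

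Ranking by the Poisson score put other loci first. The 1 peak at the score's ceiling of 100 lay in intron 2 of Gm14405 on chromosome 2, at 176615875 to 176616024, and ranked only 972 by fold enrichment (log2 2.65). Its false discovery rate was 0.507. The next score, 21.9, was shared after rounding by a peak on chromosome 12 at 55811700 to 55811949, 15.0 kb from the start of Eapp, and a peak 1417 bp upstream of Igf2bp1. A peak on chromosome 15 at 79801400 to 79801599, 38.4 kb from the start of Cbx7, scored 18.2. A peak on chromosome 17 at 6556350 to 6556499, 107.6 kb from LOC547127, scored 17.4. The linker histone genes Hist1h1d (14.7) and Hist1h1c (13.9) on chromosome 13 and the gene Gm10696 (14.6) on chromosome 3 were also among the 10. The remaining peaks lay 166.5 kb from Mup1 (13.6) and 121.6 kb from Slc10a2 (13.0), and neither had a closest transcript. Igf2bp1 was the only one of these 10 loci with the lowest false discovery rate. The Poisson scores come from a series with 1 ChIP library and carry no measure of variation between libraries.

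Where the peaks lie relative to genes bears on which genes Bcl3 could regulate. In the authors' deposited table, 687 peaks (60.8%, exact 95% interval 57.9 to 63.7%) were intergenic and 443 (39.2%, 36.3 to 42.1%) lay inside a gene. Introns held 364 peaks, exons 87, 5' UTRs 40 and 3' UTRs 8, and 94 peaks (8.3%) lay within 1 kb upstream of a TSS. By the distance from the peak midpoint to the closest TSS, 247 peaks (21.9%, 19.5 to 24.4%) lay within 5 kb, 162 (14.3%) within 1 kb and 325 (28.8%) within 10 kb. Start sites were favoured over nearby sequence. When the peaks were shifted by 50 kb to either side, 10.3% and 11.9% of the positions that could be placed lay within 5 kb of a TSS, against 23.9% and 23.7% of the same peaks unshifted (two-sided exact McNemar p = 2.29e-17 and 1.41e-13). Within 1 kb the shifted shares were 2.4% and 2.0%, against 15.8% and 15.5%. The shifted positions were chosen as a background after the data were seen. These intervals cover counting error over peaks only.

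**Figure D1:**
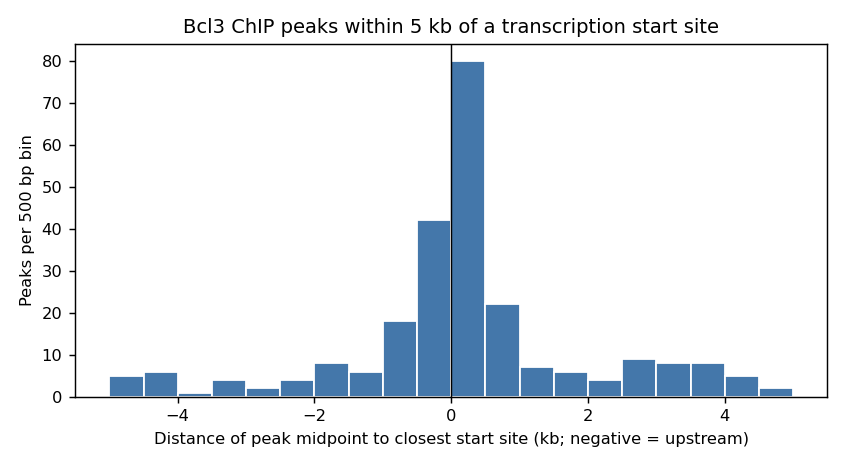
Number of Bcl3 ChIP peaks (y axis, peaks per 500 bp bin) by the signed distance of the peak midpoint to the closest transcription start site (x axis, kb, negative upstream), for the 247 peaks within 5 kb. The bin from 0 to 500 bp downstream holds 80 peaks and the bin 0 to 500 bp upstream 42.

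Peaks near a TSS lay more often downstream than upstream of it. Within 5 kb, 151 peaks lay downstream and 96 upstream, a downstream share of 61.1% (two-sided exact binomial p = 5.63e-04). The first 500 bp downstream held 80 peaks, among them those of Nme1 and Dcp1a, and the 500 bp upstream held 42. Among the 238 peaks of the lowest false discovery rate the downstream share was 59.5% (exact binomial p = 0.130). Fold enrichment did not differ detectably by distance over the whole list. The median log2 fold enrichment was 2.95 for the 247 peaks within 5 kb and 2.93 for the 883 others, a difference of 0.018 (two-sided permutation test, p = 0.530). Among the 565 peaks with the greater fold enrichment the difference was 0.144 (permutation p = 2.00e-05).

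**Figure D2:**
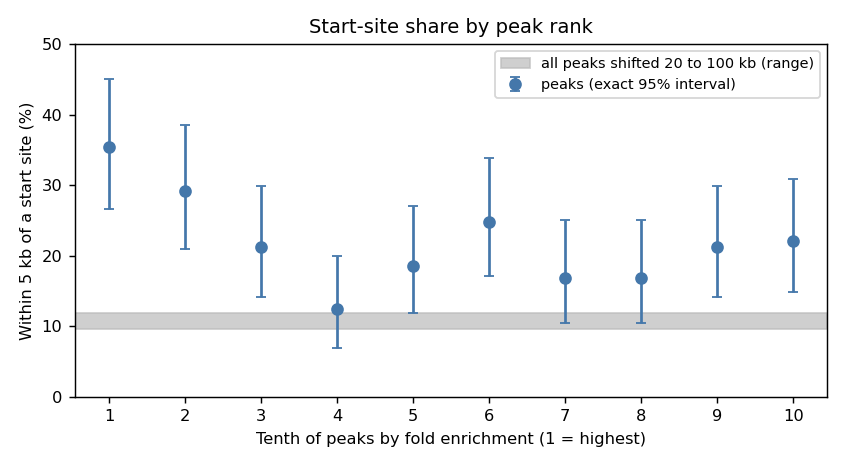
Share of peaks within 5 kb of a transcription start site (y axis, %, points with exact 95% intervals) in 10 groups of 113 peaks ranked by fold enrichment (x axis, 1 the highest). The grey band spans the shares of all peaks shifted by 20 to 100 kb, 9.6 to 11.9%, and the highest-ranked group stands at 35.4%.

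Genes of the pluripotency network were among the genes closest to Bcl3 peaks. From the core list, Mybl2 (log2 fold enrichment 3.66), Dppa5a (3.14), Fgf4 (3.08) and Zfp42 (2.82) were each the closest gene of a peak. From the naive list, Esrrb (3.77), Klf2 (3.40 and 2.73 at its 2 peaks), Zfp42 (2.82) and Tfcp2l1 (2.77) were. Dppa5a had its peak 3723 bp downstream of the TSS, beyond the end of the gene, and Zfp42 in intron 1, 1038 bp from the TSS. The Fgf4 peak lay 6272 bp downstream of the TSS, past the gene's end. The Klf2 peaks lay 5414 and 4389 bp downstream of the TSS, both past the gene's end, and the Tfcp2l1 peak lay in intron 2. Mybl2 fell outside the naming rule and is named because it completes a count of 4. False discovery rates were 0.179 for Esrrb, Mybl2 and the stronger Klf2 peak, 0.234 for Dppa5a and 0.251 for Fgf4. They were 0.372 for Zfp42, 0.402 for Tfcp2l1 and 0.429 for the other Klf2 peak. The closest gene was assigned for 623 of the 1130 peaks and gave 552 protein-coding genes. In all 623 the peak midpoint lay inside the listed transcript or at most 7954 bp from it. Each list had 4 of 20 genes among these, against 0.504 expected from 21900 protein-coding genes (odds ratio 9.73, 95% interval 2.36 to 30.3; two-sided Fisher's exact p = 0.00140, 0.0147 after Benjamini-Hochberg adjustment over 21 lists). The lists share Zfp42, so their tests are not independent. Neither list passed the adjustment among the 565 peaks with the greater Poisson score, where each had 1 gene (odds ratio 3.99, adjusted exact p = 0.902). Neither passed against a background of the wider annotation's genes, with all peaks kept (core list odds ratio 4.94, adjusted exact p = 0.120; naive list odds ratio 9.17, 0.0594). The naive list also fell to 2 genes (odds ratio 8.39, adjusted exact p = 0.155) among the 565 peaks with the greater fold enrichment, and to 3 (odds ratio 6.97, 0.0875) without the top 1% of peaks, which include the Esrrb peak. Among the 238 peaks of the lowest false discovery rate the core list had 1 gene and the naive list 2 (odds ratios 8.48 and 18.0, adjusted exact p = 0.446 and 0.0710). With every gene of the wider annotation counted, the naive list did not pass (odds ratio 1.80, adjusted exact p = 0.380). The core list did, with 17 of 20 genes (odds ratio 8.37, adjusted exact p = 9.09e-04). That setting counts 8850 of the 21900 protein-coding genes, and the peaks can lie far away. The nearest listed peak of Sox2, a core list gene, lay 658.9 kb from its TSS.

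**Figure D3:**
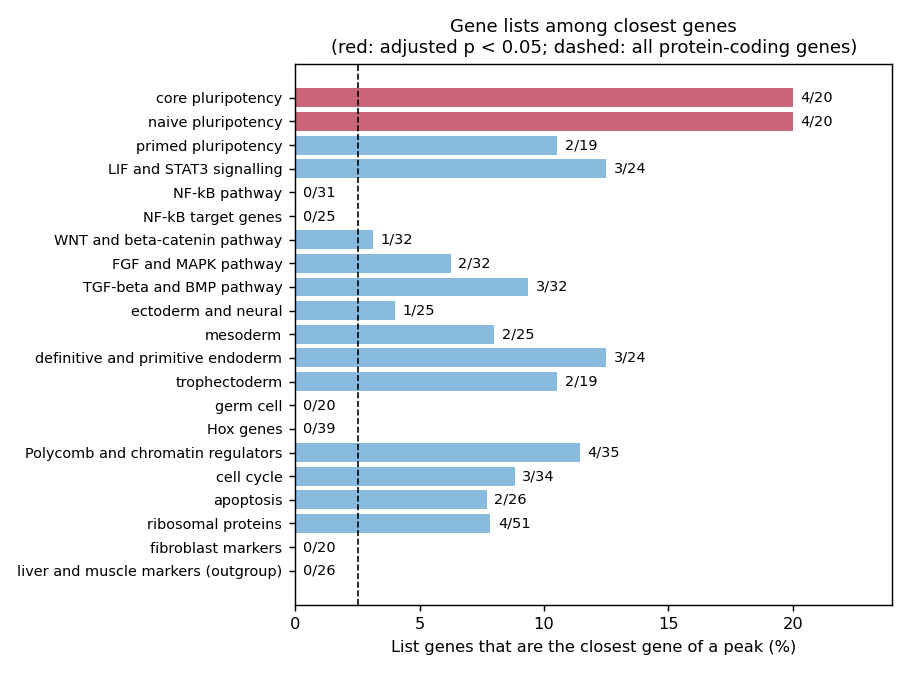
Share of the genes of each fixed list that are the closest gene of a Bcl3 ChIP peak (x axis, %), with the number of genes over the list size beside each bar. The dashed line marks the share over 21900 protein-coding genes, and the core and naive pluripotency lists (4/20 each, red) passed the adjustment over 21 lists.

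**Figure D4:**
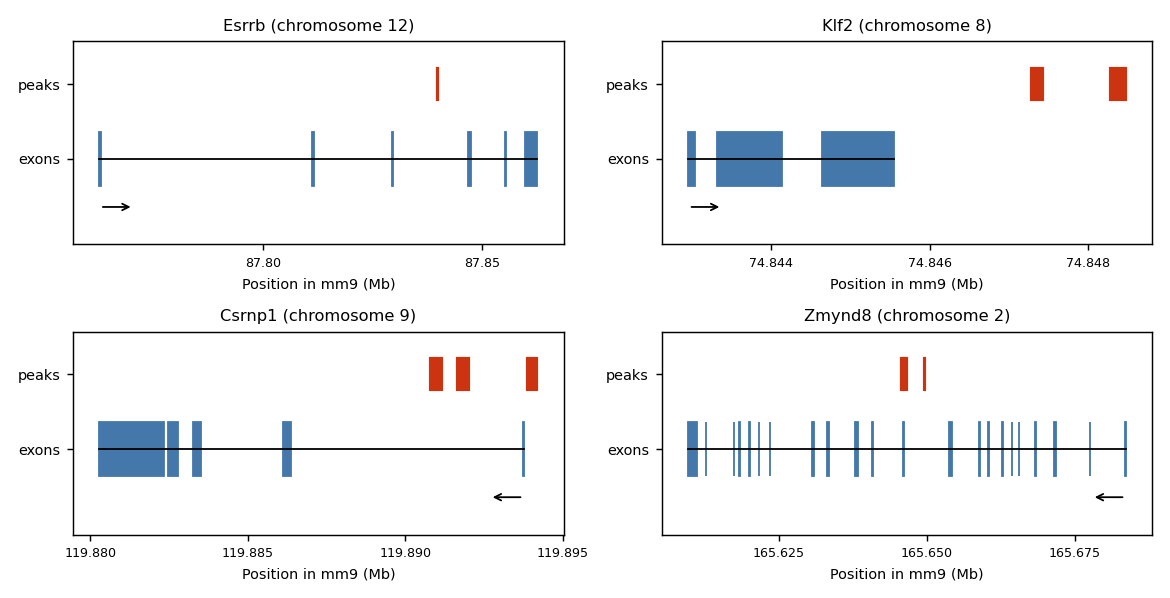
Position of Bcl3 ChIP peaks (red) and of the exons of the listed transcript (blue) at Esrrb, Klf2, Csrnp1 and Zmynd8 (x axis, position in mm9, Mb). Arrows mark the direction of transcription. The Esrrb peak lies in intron 3 and both Klf2 peaks lie past the end of the gene.

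The other 19 lists did not pass the adjustment for the closest gene, although 15 of all 21 lay above their expected number and 7 had an unadjusted Fisher's exact p under 0.05. Of the LIF and STAT3 list, Lifr (log2 fold enrichment 3.26, 128 bp from a listed TSS), Tfcp2l1 and Socs3 had a peak, 3 of 24 genes (odds ratio 5.55, adjusted exact p = 0.0914). Lifr had another peak 272 bp upstream of a listed TSS (2.97). Among Polycomb and chromatin regulators, 4 of 35 genes had a peak (odds ratio 5.02, adjusted exact p = 0.0788), including Cbx7 (2.90) and Hdac2 (2.50). The endoderm list had 3 of 24 (adjusted exact p = 0.0914), including Sox17 with a peak 194 bp upstream of its TSS (3.23) and Foxa1 (2.55). Ribosomal protein genes had 4 of 51 (adjusted exact p = 0.138), Rps20 (3.41), Rps27a, Rpl5 (3.07) and Rps15 (2.65). The TGF-β and BMP list had 3 of 32 (adjusted exact p = 0.138), with Bmp4 (3.45) and Nodal (2.55). The cell cycle list had 3 of 34 (adjusted exact p = 0.141), with Cdk4 (3.61) and Ccne1 (2.86), and the apoptosis list had 2 of 26 (0.243), with Bax (3.58). Trophectoderm genes, with Tead4 (3.71) and Bmp4, and primed pluripotency genes, with Nodal, had 2 of 19 each (adjusted exact p = 0.172). Mesoderm genes, Twist1 (3.46) and Nkx2-5 (3.17), were 2 of 25 (0.243), and the FGF and MAPK genes Fgfr1 (3.48) and Fgf4 were 2 of 32 (0.311). Wnt5a (2.78) was 1 of 32 genes of the WNT list (0.782). The neural list had 1 of 25 (0.708), Pax6 (3.45), which fell outside the naming rule. The named peaks differed in false discovery rate. It was 0.179 for Tead4, Cdk4 and Bax, 0.402 for Wnt5a, 0.592 for Nodal and Foxa1, and 0.617 for Hdac2.

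No gene of the NF-κB lists was closest to a peak. The 507 peaks without a closest transcript could not count toward any list. The NF-κB pathway list had 0 of 31 genes, which allows a share of up to 9.68%, and the NF-κB target list 0 of 25, which allows up to 12%, each with an adjusted p of 1. The germ cell list (0 of 20, up to 15%), the fibroblast list (0 of 20, up to 15%) and the liver and muscle list (0 of 26, up to 11.5%) also had none (adjusted exact p = 1 each). Hox genes had 0 of 39, which allows up to 7.69% (adjusted exact p = 0.823). With every gene of the wider annotation counted, which reaches farther, 29 Hox genes were listed (odds ratio 4.29, adjusted exact p = 4.81e-04). That annotation lists up to 21 genes per peak, so neighbouring Hox genes can share a peak. They are then not independent, and the p is likely too small. At these list sizes a depletion was not detectable, since fewer than 1 gene was expected in each of these lists. In simulations with the observed number of genes, a 20-member list raised 10-fold passed the adjustment in 69.5% of runs and one raised 5-fold in 20.5%. These simulations ignored gene length.

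Counting only genes with a peak within 5 kb of the TSS, 0 of 21 lists passed the adjustment, and 6 had an unadjusted Fisher's exact p under 0.05. Ribosomal protein genes came closest, with 4 of 51 (odds ratio 6.75, 1.75 to 18.7, p = 0.00388, adjusted exact p = 0.0814). Rps27a had a peak 385 bp upstream of its TSS (log2 fold enrichment 3.32) and Rpl5 one 404 bp downstream (3.07). The core list, with Dppa5a and Zfp42, and the naive list, with Zfp42 and Klf2, had 2 of 20 each (odds ratio 8.76, adjusted exact p = 0.136). Nkx2-2, of the neural list, had a peak 3075 bp upstream (2.67), whose closest transcript was that of Nkx2-2as. The LIF and STAT3 list had 0 of 24 here, because distances came from the wider annotation. There the nearest start to the Lifr peak of 3.26, also of Lifr, was 10.8 kb away. The window held 276 protein-coding genes, fewer than the 552 closest genes.

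Of 18 loci fixed before the data were examined, 5 were the closest gene of a peak, namely Klf2, Esrrb, Tfcp2l1, Zfp42 and Socs3. The Socs3 peak lay 5670 bp upstream of the TSS with a log2 fold enrichment of 2.67 and a false discovery rate of 0.486. The rates were 0.372 for Zfp42 and 0.402 for Tfcp2l1. Only Klf2 and Esrrb had a peak at the lowest rate, 0.179. A further 10 appeared only in the authors' wider annotation, which lists up to 21 genes per peak. Among these, Nanog had its nearest peak 44.5 kb upstream of its TSS (2.61) and Myc 54.0 kb downstream (2.66). The nearest peak of Ccnd1 lay 72.3 kb downstream (3.08) and is the Fgf4 peak, 6272 bp from the Fgf4 TSS. That of Bcl3 itself lay 119.5 kb downstream (2.70). For Pou5f1 the nearest listed peak was 257.0 kb upstream, for Nfkb2 314.1 kb upstream, for Klf4 396.9 kb downstream, for Klf5 507.3 kb, for Sox2 658.9 kb and for Nfkb1 865.1 kb upstream. No listed peak was annotated to Tbx3, Stat3 or Rela. The read depth is unknown, so a locus without a listed peak is not shown to be free of Bcl3. The listed peaks are not shown to be true sites either. Their false discovery rates were 0.529 for Nanog, 0.486 for Myc, 0.463 for Bcl3 and 0.251 for Ccnd1.

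Repeated peaks at 1 gene were rare. Csrnp1 and Zmynd8 had 3 peaks each, and 27 genes had 2. At Csrnp1 the peaks lay 262 bp upstream of the TSS and 1938 and 2788 bp downstream in intron 1, with log2 fold enrichments of 3.54, 3.61 and 3.58. All 3 had a false discovery rate of 0.179. The Zmynd8 peaks lay 34.1 to 37.8 kb inside the gene, in introns 10 and 11, at 3.55, 2.97 and 2.77. Some of these peaks are neighbours. With peaks within 1000 bp merged, 1120 peaks remained. The Csrnp1 peaks in intron 1 then joined, as did the Zmynd8 peaks at 3.55 and 2.77. Tfdp2 (highest 3.58), Dlg2 (3.55) and Herpud2 (3.50) had 2 each.

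Peaks were spread over 21 chromosomes, but not in proportion to protein-coding genes (chi-square 94.1, Monte Carlo p = 1.00e-05, the smallest that 100000 resamples can give). Chromosome 11 held 44 peaks against 83.1 expected (exact binomial p = 1.97e-06, adjusted exact p = 4.14e-05) and chromosome 7 held 73 against 104.8 (adjusted exact p = 0.00438). No peak on chromosome 11 was listed before 29.4 Mb, an empty stretch of 26.4 Mb, and the low count there includes that stretch. The listed ranks ran to 1130 with 0 missing, which is also the total in the authors' deposited table. Chromosome 13 held 66 against 42.8 (adjusted exact p = 0.00438), chromosome 3 held 73 against 50.8 (0.0103) and chromosome 14 held 64 against 43.9 (0.0117). Chromosome Y held 1 peak against 13.2 (4.47e-04). The gene counts come from GRCm38.p6 and the peaks from mm9. A depletion on Y cannot be told apart from a difference between these builds, and the chi-square includes Y. Against the length of each chromosome covered by the listed positions instead, with Y left out, the peaks did not depart detectably from proportion (chi-square 24.6, Monte Carlo p = 0.172). That alternative was chosen after the data were seen.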

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

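The alternatives using the 238 peaks of the lowest false discovery rate, the distances of the closest-transcript sheet, closest genes also in the wider annotation, and chromosome length were chosen after the data were seen. Of the values answering a comparison, 30 stayed the same, 15 moved, 1 passed a threshold it had missed, 2 no longer passed, and none reversed. Staying the same meant keeping the side of the threshold for tests and lying within the interval for shares. For counts it meant lying within a set ratio of the main count. Of the tests of single lists, 302 stayed on their side, 9 no longer passed, all of them core or naive pluripotency by closest gene, and 4 newly passed. No peak list of at most 5% false discovery rate existed (0 peaks), and the stricter lists held 565 and 238 of the 1130 peaks by construction.

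The share of peaks within 5 kb of a TSS was 31.1% in the 238 peaks, and it was 14.3% and 28.8% with windows of 1 and 10 kb, which follows from the window. The downstream share in the 238 peaks, 59.5%, kept its direction on fewer peaks (exact p = 0.130). The difference in log2 fold enrichment near a TSS rose to 0.144 in the 565 peaks of greater fold enrichment, and the cause was not tested. The downstream share was 59.5 to 66.8% across its alternatives.

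Gene lists passing the adjustment for the closest gene numbered 2. They were 0 in the 565 peaks of greater Poisson score, 1 (core pluripotency) in the 565 of greater fold enrichment, where the naive list had an odds ratio of 8.39 and an adjusted p of 0.155, 1 (core) without the top 1% of peaks and 0 in the 238 peaks. They were 0 against a background of the wider annotation's genes, where the core list had an adjusted p of 0.120 and the naive list 0.0594. With every gene of the wider annotation they were 4, namely core pluripotency (odds ratio 8.37), TGF-β and BMP (2.82), Hox (4.29) and cell cycle (3.09). That setting counts 8850 of 21900 protein-coding genes, with up to 21 genes per peak. Neighbouring genes such as Hox genes are therefore not independent there, and a listed gene can lie far from its peak. In the 238 peaks the core list had an odds ratio of 8.48 (adjusted p 0.446) and the naive list 18.0 (0.0710), against 9.73 for each over all peaks. Fewer peaks leave fewer list genes, while the cause of the other changes was not tested. Within 5 kb of the TSS, 1 list passed in the 238 peaks (trophectoderm, adjusted exact p = 0.0466), and 0 in the other alternatives run.

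Chi-square over chromosomes was 24.6 (p = 0.172) against chromosome length, so the departure from gene number was not seen against length. Fixed loci with a peak numbered 15 with every gene of the wider annotation, which reaches farther, and 2 in the 238 peaks (Klf2 and Esrrb).

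No paired analysis was possible because each group had 1 library. The κB motif alternatives were not run, since a genome of this build was not used here. Without replicates or read depth, the list sizes limit these tests.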

Other observations

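The gene families, the reassignment among listed genes, the comparisons with ribosomal protein genes and with gene clusters, the groups by rank and the empty stretches of chromosomes were tested only after the related results had been seen. The gene length and shifted-position tests were set out before their results were seen.

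Histone genes stood out among genes with a peak near the TSS. Of 67 core histone and linker histone genes, 17 had a peak within 5 kb of the TSS, against 0.844 expected (odds ratio 28.3, 15.1 to 50.7, Fisher's exact p = 5.97e-18, adjusted over 8 family tests 4.78e-17). Those 17 genes lay next to only 8 peaks, all on chromosome 13, where histone genes sit close together, so the genes are not independent and the p is too small. By closest gene, 8 of the 67 had a peak (odds ratio 5.31, exact p = 2.73e-04, adjusted p = 4.37e-04), among them Hist1h1c and Hist1h1d. The ribosomal protein family had 7 of 85 genes with a peak within 5 kb (odds ratio 7.19, 2.77 to 15.7, exact p = 9.99e-05, adjusted p = 2.00e-04). Olfactory and vomeronasal receptor genes were under-represented among closest genes, with 11 of 1463 against 36.9 expected (odds ratio 0.279, exact p = 4.10e-07, adjusted p = 1.64e-06). How reads were assigned between similar gene copies is not given in the sources used here.

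The joined core and naive pluripotency lists had 7 of 39 genes as the closest gene of a peak, Dppa5a, Esrrb, Fgf4, Klf2, Mybl2, Tfcp2l1 and Zfp42 (odds ratio 8.55, 3.17 to 19.8, exact p = 4.75e-05). Gene length stays open, because only 27 of the 39 genes (69.2%) were in the wider annotation and had a length, which makes the check void. Among those 27, 7 had a peak against 1.44 in 10000 draws of genes of matched length from that annotation, with a one-sided p of 2.00e-04. Both lists had been picked because they passed, which these p-values do not take into account. A general pull toward regulatory genes stays open too. Of the 411 other genes in the 18 regulatory lists 5.6% had a peak. Single lists reached 11.4% (Polycomb and chromatin) and 12.5% (LIF and STAT3, and endoderm). The genes with a peak in the LIF and STAT3 list include Tfcp2l1, which is also in the naive list. When the 30 genes with a peak were reassigned at random among the 450 genes of these lists, the most extreme of the 153 pairs of lists was as extreme as the core and naive pair with a permutation p of 0.351. Recovery of any highly transcribed gene stays open as well. The ribosomal protein family was over-represented too (odds ratio 3.502, 1.36 to 7.61, exact p = 0.00565), and the pluripotency interval overlaps that one. The planned list of 51 ribosomal protein genes did not pass by closest gene (odds ratio 3.31, 0.863 to 9.09, adjusted exact p = 0.138). Open or active chromatin that is recovered whatever the antibody may therefore account for part of the pluripotency genes. Bcl3 bound near these genes is another open explanation, untested because the design has no cells without Bcl3 and the input was not analysed here.

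Peaks were concentrated at start sites, and gene-dense surroundings as the whole cause are argued against by the positions 50 kb away, where the larger of both exact McNemar p-values was 1.41e-13. Among the 226 with the greatest fold enrichment, such as those of Nme1, Dcp1a and Tead4, 32.3% lay within 5 kb of a TSS against 19.2% of the other 904 (odds ratio 2.00, 1.42 to 2.80, Fisher's exact p = 4.58e-05). The cut was set after the shares by rank had been seen, and these did not fall steadily, with 35.4%, 29.2%, 21.2% and 12.4% in the first groups of 113 peaks, 24.8% in group 6 and 22.1% in group 10. Over the whole list the median fold enrichment near and far from a TSS did not differ detectably (permutation p = 0.530). A larger part of true binding sites among the top ranks could give this, and so could open chromatin at promoters, and no biological explanation was tested.

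The peaks of Hist1h1c and Hist1h1d, with scores of 13.9 and 14.7, lay in the histone gene cluster of chromosome 13. Of the 20 greatest scores, 3 (15.0%) lay within 100 kb of at least 3 like-named genes, all 3 of them in that cluster, against 48 of the other 1110 (4.3%, 3.2 to 5.7%; Fisher's exact p = 0.05741). Gene copies with unlike names, or farther than 100 kb from a peak, were not counted. Reads shared between gene copies could raise such scores, but with 3 peaks this and a chance excess cannot be told apart.

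Chromosome 11 had no peak before 29.4 Mb, while the first peak of every other chromosome except Y lay between 3.00 and 8.93 Mb. The empty stretch of 26.4 Mb was the longest in the list, and the next was 17.2 Mb, on chromosome 14. In 10000 uniform placements of the same number of peaks per chromosome, 119 had a stretch at least as long, and the median longest stretch was 16.6 Mb. Uniform placement ignores genes and unmappable sequence, and the stretch was chosen as the longest seen.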
